A study of Homo sapiens with 33 samples.

How the data were processed

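RNA immunoprecipitation followed by hybridisation to Affymetrix exon arrays was carried out in 2 human cell lines of the ENCODE project: GM12878, a B-lymphoblastoid line, and K562, an erythroleukaemia line. The labels described 33 arrays in 9 groups. GM12878 had 6 input arrays, 3 HuR, 3 PABP and 1 G10 immunoprecipitate, and K562 had 8 input arrays, 3 HuR, 4 PABP, 3 Imp and 2 G10 immunoprecipitates. HuR is the product of ELAVL1, PABP of PABPC1 and Imp of IGF2BP1, and the list for G10 carries the name T7Tag. Each array was placed in its group by its title. The labels do not say whether arrays of a group came from separate cultures, so the authors' p-values may measure technical spread.

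The values used here were 7 lists that the authors made, 1 for each immunoprecipitation in each cell line. No values for single arrays were used here, so replicate errors, leave-one-out fits and tests across arrays were not computed. The number of arrays, from 1 to 4 immunoprecipitates per list, limits the precision. All lists held the same 17880 features. The deposited enrichment value was read as a log2 value, because it ran below 0, although the base is not given in the sources used here. The deposited score used base 2, but that factor may belong to the p and does not settle the base of the value. All folds named here rest on this reading. The comparison arm of each value (input or another sample) is not given in the sources used here either. The authors deposited a -log10 p beside each value; it was read as an unadjusted p, one-sided toward enrichment, because it lay above the middle of its range at every value below 0. In the GM12878 G10 list every -log10 p was 0, so that list had no p to use. The deposited score, a display shade, was either 1 or 100 plus a multiple of the product of value and -log10 p, within a tolerance of 1 for 100% of those features. Features with a score above 1 are called marked present, after the wording of the authors' list titles, and were read as features detected in all immunoprecipitates of the list. That reading is not stated in the sources used here. The submitters' processing notes name Affymetrix Power Tools, RMA and PLIER, with no role or version. RMA and PLIER summarise probe intensities into 1 value per feature, and the ratios of weak features may be distorted.

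The genome build of the lists is not given in the sources used here. It is not GRCh38, the assembly of the gene table at hand, because features ended beyond the last GRCh38 gene on chromosomes 3, 4 and 19. On chromosome 19 the last feature ended at 63804637 and the last GRCh38 gene at 58599484. The features carry array numbers, and the sources used here do not pair these with gene names. The 18 gene lists fixed beforehand, the mRNAs of ELAVL1, PABPC1 and IGF2BP1, and the 3′ UTR sequence tests were therefore not run. Features are given by array number and 1-based coordinates as deposited, with at most 2 high and 2 low features for each protein. The rule fixed beforehand named the features of highest and lowest value past the p threshold. As no feature passed after adjustment, it was applied to the deposited p: at most 0.05 for high values, and at least as extreme on the other side for low values. Features shared by both lines were those of highest smaller value among features marked present and enriched in both. Features on the Y chromosome were left out of named features, chromosome and window results.

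Enriched features were defined before the data were examined as those with a value of at least 1 (a fold of 2) and a Benjamini-Hochberg adjusted p of at most 0.05 within the list. Alternatives were a fold of 1.5 or 4, a deposited p of at most 0.05 or 0.001, an adjusted p of at most 0.1, features marked present, and values centred on the list median. Overlaps of lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 78 tests. The tests covered the 500 features of highest value, the 500 of lowest value and the features enriched at the deposited p, each over the 17880 features, and the highest 10% of features marked present in both lists, over those features only. Pearson and Spearman correlations were computed across features for 21 pairs of lists. Features are not independent replicates, so no p is given for the correlations and the p-values of tests over features are too small. Lists of the same cell line may share input arrays, and part of their likeness may come from that; this was not simulated, as it needs values for single arrays.

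Relations with genomic span and with position were added after the data were examined. The span is the distance from the first to the last base of a feature, introns included. Intervals of rank correlations came from 1000 bootstrap resamples of features. Windows of 1 Mb with at least 8 features (799 windows) were tested by Fisher's exact test for the share of features in the highest and the lowest 10% of a list, adjusted over 11186 tests, and chromosomes likewise over 483 tests. The window scan was tested on simulated lists of the same 799 windows, made by shuffling the HuR values of GM12878 over all features. It recovered 20 of 20 windows shifted by 2 SD and 1 of 20 shifted by 1 SD, with 0 false windows. Each simulated list was adjusted by itself and not over 11186 tests, so recovery in the scan of the deposited lists may differ. Shuffling also removes any likeness of neighbouring features, so the count of false windows does not carry over to the deposited lists. All shifted windows held at least 20 features, so recovery in smaller windows was not tested. Mitochondrial features were set against random sets of as many features in a two-sided permutation test with 100000 draws, adjusted over 7 lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.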

Results

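The arrays measured which transcripts came down with the RNA-binding proteins HuR, PABP and Imp in GM12878 and K562 cells. HuR (ELAVL1) binds U-rich and AU-rich elements of mRNAs, PABP (PABPC1) binds poly(A) tails, and Imp (IGF2BP1) is an mRNA-binding protein of the cytoplasm. G10, whose list carries the name of an epitope tag, was set beside these proteins here as a comparison, although its role is not given in the sources used here. The data comprised 14 input arrays and 19 immunoprecipitate arrays, 13 arrays in GM12878 and 20 in K562. The authors' lists gave 1 enrichment value per feature for HuR, PABP and G10 in both lines and for Imp in K562. Each list held 17880 features with a median genomic span of 37342 bp. Values are the authors' and carry no replicate error that could be computed here.

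Over all features the HuR lists had the highest medians of the 7 lists. The median value was 2.24 in GM12878 and 1.29 in K562, against 1.09 and 0.79 for PABP, 0.08 for Imp, and 0.51 and -0.41 for G10 in the same order of lines. Values above 0 were listed for 17325 features in the HuR list of GM12878 and for 2854 in the G10 list of K562. As whole lists were shifted in this way, positions within a list are mainly compared from here on. Counts and overlaps at the deposited p use the values as deposited unless centring is named. They therefore carry these shifts and do not compare levels between proteins. The mark for presence in all immunoprecipitates was carried by 5151 features for HuR in GM12878, 3808 for HuR in K562, 1883 and 225 for PABP, 2675 for Imp, and 2277 and 944 for G10. It was carried in all lists by 192 features and in none by 12216. In GM12878 marked features had a higher median than the other features for HuR (3.43 against 2.03) and PABP (1.34 against 1.07), and in K562 a lower one for both (1.20 against 1.29 and 0.13 against 0.80).

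**Figure D1:**
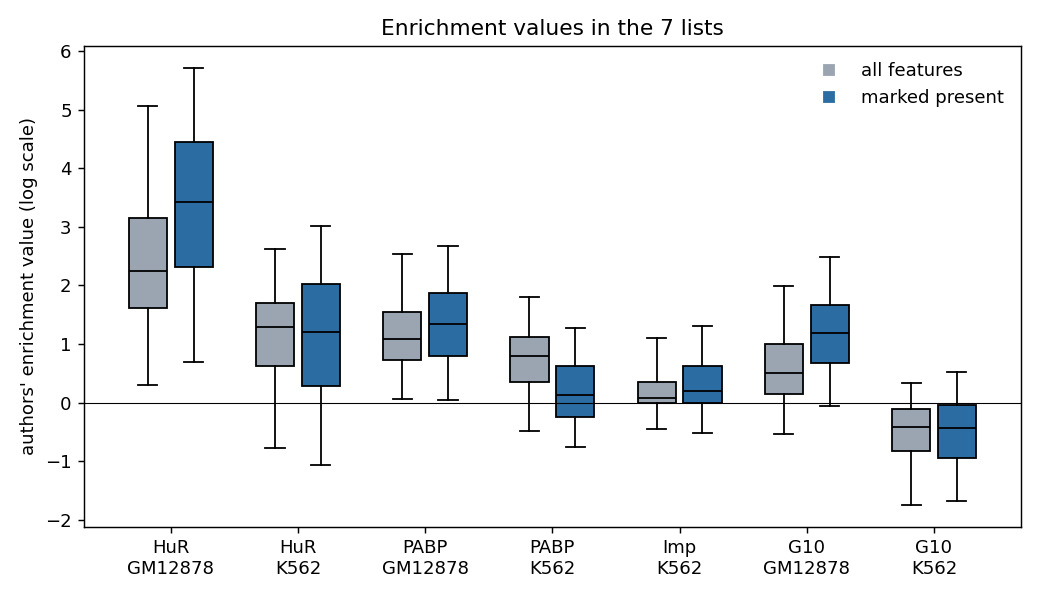
Authors' enrichment values on a log scale for all features (grey) and features marked present (blue) in each of the 7 lists. Boxes span the quartiles with the median as a line, and whiskers reach the 5 and 95 percentiles; medians of all features run from 2.24 for HuR in GM12878 to -0.41 for G10 in K562.

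No feature reached the enrichment threshold of a 2-fold value with an adjusted p of at most 0.05 in any of the 6 lists with p-values (Benjamini-Hochberg on the authors' p). The smallest adjusted p was 0.0501 for HuR in K562, just over the threshold. It was 0.0844 for HuR in GM12878, 0.104 and 0.246 for PABP, 0.130 for Imp and 1 for G10 in K562. At the p as deposited, 10201 features of the HuR list passed in GM12878 and 9531 in K562. For PABP, 7282 passed in GM12878 and 2176 in K562, for Imp 983, and for G10 in K562 78. At an unadjusted p of at most 0.05 without the fold, the counts were 10211, 10720, 8326, 3023, 3390 and 172. With the value centred on the list median, the counts at the deposited p became 4106 and 1318 for HuR, 1775 and 279 for PABP, 832 for Imp and 144 for G10.

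High HuR values were shared between GM12878 and K562 more often than in independent lists. Of the 500 highest features in each line, 197 were shared, against 13.98 for independent lists (Fisher's exact test, odds ratio 36.6, adjusted p = 6.92e-183). The 500 lowest shared 203. With enrichment at the deposited p the odds ratio was smaller, 3.13, with 6654 shared features against 5438 for independent lists. Across all features the HuR values of the lines correlated at r = 0.63 (Spearman 0.59), and over the 3489 features marked present in both at r = 0.81. Over features marked present in neither line the correlation was 0.67, so the likeness was not confined to marked features. In the authors' deposited table, feature 3367183 (chromosome 11, 27472331 to 27484875, minus strand) had values of 7.04 in GM12878 (p = 0.0105) and 4.70 in K562 (p = 0.00666). In the authors' deposited table, feature 3724969 (chromosome 17, 43373775 to 43381666, plus strand) had values of 5.69 (p = 0.0161) and 4.53 (p = 0.0258). These were the leading features among 1463 marked present and enriched at the deposited p in both lines. At the low end, feature 2899102 (chromosome 6, 26153430 to 26154989) had a value of -3.60 for HuR in K562 in the authors' deposited table, with a one-sided p toward enrichment of 0.952. Feature 3939952 (chromosome 22, 22977557 to 22991658) had -3.01 for HuR in GM12878 in the authors' deposited table, with a p of 0.969. Neither low feature was marked present.

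PABP values were likewise shared between the lines. The 500 highest features shared 236, against 13.98 for independent lists (Fisher's exact test, odds ratio 58.0, adjusted p = 3.38e-247), and the 500 lowest shared 199. In K562, 5896 features had a PABP value of at least 1, but only 22 of these were marked present. At most 22 of the 500 highest in K562 were therefore marked present. The correlation was 0.61 across all features (Spearman 0.56) and 0.85 over the 206 features marked present in both lines. Over features marked present in neither line it was 0.61. With enrichment at the deposited p the odds ratio was smaller, 1.43, with 1053 shared features against 886 for independent lists. In the authors' deposited table the highest PABP value in GM12878 past the deposited p was 5.82, at feature 3081613 (chromosome 7, 156166338 to 156166665, p = 0.0264). In K562 it was 5.10 in the authors' deposited table, at feature 3201300 (chromosome 9, 21340318 to 21340886, p = 0.0368). Among features past the deposited p on the low side, the lowest values in the authors' deposited table were -5.03 at feature 2895945 in GM12878 (chromosome 6, 14232105 to 14232948) and -4.75 at feature 2663504 in K562 (chromosome 3, 12923896 to 12924477). None of these 4 features was marked present, and all were shorter than 1 kb.

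Across all features HuR and PABP values were nearly uncorrelated within each line. Within GM12878 their values correlated at r = 0.02 and within K562 at 0.03, and over features marked present in both at 0.04 and 0.03. Over features past the deposited p in both lists the correlation was higher, 0.19 in GM12878 and 0.30 in K562. Across the lines it was -0.15 for HuR in GM12878 with PABP in K562 and -0.13 for HuR in K562 with PABP in GM12878. The 500 highest features of HuR and PABP shared 22 in GM12878 (adjusted p = 0.0470) and 21 in K562 (adjusted p = 0.0829), against 13.98 for independent lists (Fisher's exact test). The 500 lowest features shared 43 in GM12878 (odds ratio 3.48, Fisher's exact test, adjusted p = 1.19e-10) and 41 in K562 (odds ratio 3.29, adjusted p = 1.33e-09). At the deposited p the lines went in opposite directions: 3871 shared features against 4155 for independent lists in GM12878, and 1771 against 1160 in K562. Lists of 1 line may share input arrays, so these counts are not independent of a common comparison arm.

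Imp values in K562 followed those of PABP more than those of HuR. Imp and PABP correlated at r = 0.43 across all features and 0.54 over the 225 features marked present in both, and their 500 highest features shared 161 (Fisher's exact test, odds ratio 23.9, adjusted p = 4.17e-130). At most 22 of the 500 highest PABP features were marked present for PABP. With enrichment at the deposited p Imp and PABP shared 81 features, fewer than the 120 of independent lists. Imp and HuR correlated at -0.09 across all features and at 0.17 over the 2348 marked present in both, so the sign depended on the feature set. Their 500 highest features shared 26 (Fisher's exact test, adjusted p = 0.00311) and their 500 lowest shared 51 (odds ratio 4.28, adjusted p = 2.40e-15). At the deposited p they shared 158 against 524 for independent lists. The authors' deposited table listed the highest Imp values past the deposited p at feature 3752258 (3.30, chromosome 17, 26654715 to 26665228, p = 0.00982) and feature 2947095 (3.28, chromosome 6, 27966073 to 27966599, p = 0.0273). Among features past the deposited p on the low side, the lowest in the authors' deposited table were feature 2565902 (-5.62, chromosome 2, 97465656 to 97494104) and feature 3717034 (-3.89, chromosome 17, 26385095 to 26386805). None of the 4 was marked present.

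Across all features and among the 500 highest, the G10 immunoprecipitation shared its ranking with PABP in both lines and with Imp in K562. It shared less with HuR, and much less only in K562. PABP and G10 correlated at r = 0.56 in GM12878 and 0.55 in K562, and at 0.83 in both lines over features marked present in both. Over features marked present in neither list the correlation was 0.53 in GM12878 and 0.55 in K562. Imp and G10 correlated at 0.34, and at 0.52 over features marked present in both. HuR and G10 correlated at 0.26 in GM12878 and at -0.05 in K562. Spearman correlations with G10 were 0.58 in GM12878 and 0.57 in K562 for PABP, 0.37 in K562 for Imp, and 0.32 and -0.02 for HuR. Over features past the deposited p in both lists in K562, the correlation with G10 was 0.055 for PABP (15 features). It was 0.17 for HuR (32 features) and 0.62 for Imp (138 features). The order of PABP and HuR did not hold in these small sets. The 500 highest G10 features shared 180 with PABP and 58 with HuR in GM12878. In K562 they shared 139 with PABP, 134 with Imp and 23 with HuR, against 13.98 for independent lists (Fisher's exact test, adjusted p from 0.0242 for HuR in K562 to 4.27e-157 for PABP in GM12878). At most 22 of the 500 highest PABP features in K562 were marked present for PABP. At the deposited p in K562, 61 of the 78 G10 features were also enriched for Imp, against 4.29 for independent lists, and 10 for PABP, against 9.49 (Fisher's exact test, adjusted p = 0.862). With HuR they shared 13, fewer than the 41.6 of independent lists (odds ratio 0.174, Fisher's exact test, adjusted p = 4.90e-11), the opposite direction from the 500 highest. Between the lines the G10 values correlated at 0.29, and at 0.57 over features marked present in both. Feature 3081613, which headed the PABP list of GM12878, also had the highest G10 value there, 6.29 in the authors' deposited table. The G10 list of GM12878 came from 1 array and that of K562 from 2.

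**Figure D2:**
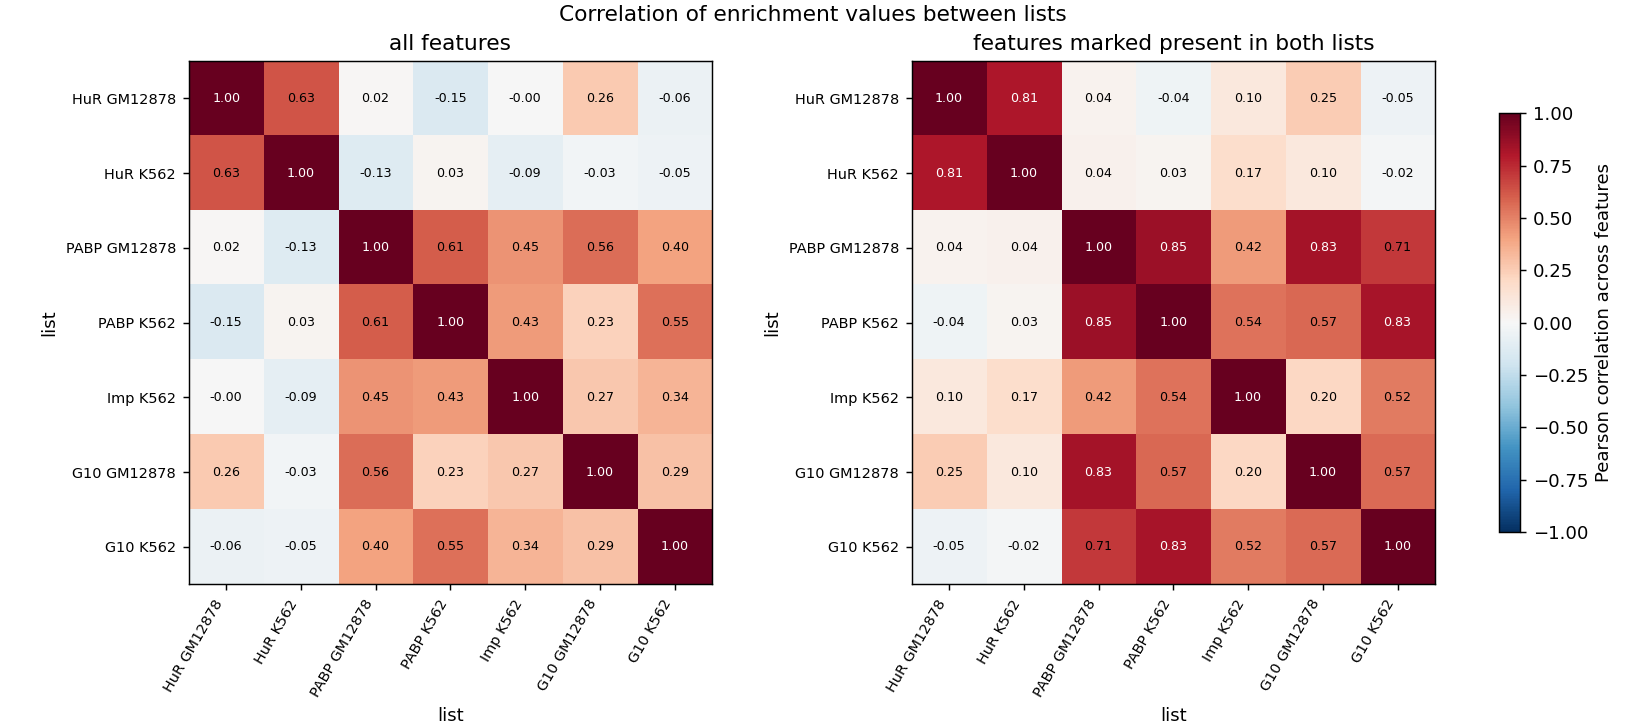
Pearson correlations of enrichment values across features between all pairs of the 7 lists, over all 17880 features (left) and over features marked present in both lists (right), with colour and printed number giving the correlation from -1 to 1. HuR lists pair with each other (0.63 and 0.81), while PABP pairs with G10 in each line (0.56 and 0.55 left, 0.83 and 0.83 right).

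Transcripts from long genomic regions were more often marked present in every list. In GM12878, HuR marked 49.0% of the 20% of features with the longest span and 3.55% of the 20% with the shortest. For PABP in K562 the shares were 1.48% and 0.364% (Fisher's exact test, adjusted p = 6.47e-07, the weakest of the 7 lists). Among features marked present, short features had higher values than long ones for PABP, with a rank correlation of value with span of -0.36 in GM12878 (95% bootstrap interval -0.408 to -0.322) and -0.35 in K562 (-0.479 to -0.214). The same held for Imp (-0.24) and for G10 (-0.18 in GM12878 and -0.28 in K562). For HuR the relation over its own marked features was near 0, with 0.01 in GM12878 (-0.0133 to 0.0434) and -0.00095 in K562 (-0.0330 to 0.0325). The marked features differ between the lists. Over the 777 features marked in every list but that of PABP in K562, HuR values were higher in long features, with 0.22 in GM12878 (0.159 to 0.293) and 0.11 in K562 (0.0482 to 0.182), while PABP (-0.28 and -0.25), Imp (-0.15) and G10 (-0.12 and -0.25) kept negative values. Across all features, HuR values were also higher in long features, with 0.27 in GM12878 and 0.08 in K562, and G10 in GM12878 had the opposite sign from that among marked features, at 0.10. The median PABP value of marked features in GM12878 was 2.23 in the shortest 20% and 1.01 in the longest.

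**Figure D3:**
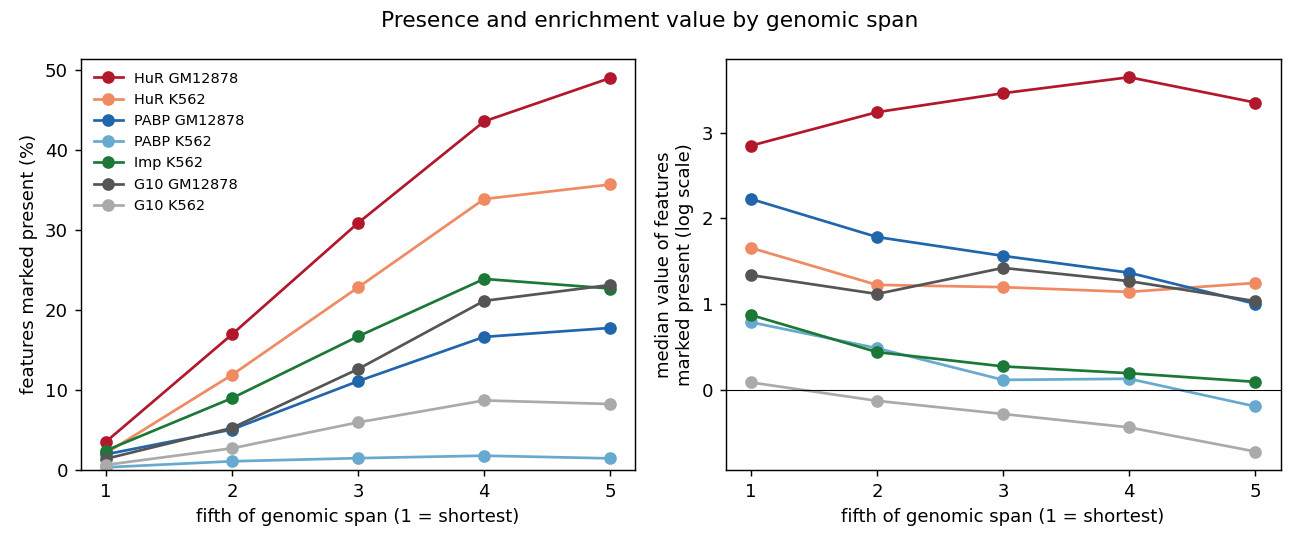
Percentage of features marked present (left) and median enrichment value of the marked features on a log scale (right) in 5 equal groups of genomic span, from the shortest to the longest 20%, for each of the 7 lists (lines). The share marked present for HuR in GM12878 runs from 3.55% to 49.0%, and the PABP median in GM12878 from 2.23 to 1.01.

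By position in the genome, low HuR values gathered on chromosome 19 and in other feature-dense regions. On chromosome 19, 23.5% of 1231 features were in the lowest 10% of the HuR list of GM12878 (Fisher's exact test, adjusted p = 3.34e-44) and 15.03% in that of K562 (adjusted p = 2.26e-07). G10 values were low there as well, with 15.03% in the lowest 10% in GM12878 (Fisher's exact test, adjusted p = 2.26e-07) and 12.8% in K562 (adjusted p = 0.00478), while PABP (8.85% in each line) and Imp (10.4%) did not pass in that direction. PABP and Imp had an excess of high values there, with 13.8% of the features in the highest 10% for PABP in GM12878, 16.7% for PABP in K562 and 12.6% for Imp (Fisher's exact test, adjusted p = 0.000118, 2.11e-12 and 0.00976). For PABP 56 of the 1231 features were marked present in GM12878 and 16 in K562, against 170 and 206 in the highest 10%. Most of these high PABP values were therefore at features not marked present. For Imp 79 were marked present, against 155 in the highest 10%. Of the chromosome 19 features 13.5% were marked present for HuR in GM12878, against 28.8% of the list. Of the 799 windows of 1 Mb, 16 held too many features of the lowest 10% for HuR in GM12878. The leading window lay at 10 to 11 Mb of chromosome 19, with 18 of 33 features (Fisher's exact test, adjusted p = 2.45e-06). HuR in K562 had 3 such windows, of which those at 65 to 66 Mb of chromosome 11 and 130 to 131 Mb of chromosome 9 also passed in GM12878. PABP had an excess of high values at 12 to 13 Mb of chromosome 19 in both lines, with 12 of 36 features in the highest 10% in GM12878 (Fisher's exact test, adjusted p = 0.0427) and 13 of 36 in K562 (adjusted p = 0.0160). That window was also among the 16 of low HuR values in GM12878. With the outer 5% of features, the PABP window no longer passed in either line (Fisher's exact test, adjusted p = 0.270 and 0.951), nor did either shared HuR window in K562 (0.241 and 1). In GM12878, 5 windows of low HuR values passed in that setting, not all of them among the 16. Of the 16, those at 10 to 11 Mb of chromosome 19 and 65 to 66 Mb of chromosome 11 passed again. The window at 77 to 78 Mb of chromosome 17 also did. The others did not, among them that at 130 to 131 Mb of chromosome 9 (Fisher's exact test, adjusted p = 0.120). With windows of 2 Mb, 30 windows of low HuR values passed in GM12878.

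Imp values were high at 26 to 28 Mb of chromosome 6, on the arm that carries the major histone gene cluster. There 24 of 65 features (36.9%) were in the highest 10% of the Imp list (Fisher's exact test, odds ratio 5.33, adjusted p = 4.12e-08), with a median of 0.54 against 0.08 for the list. The region was chosen after its windows had passed the scan, so this p is not independent of it. HuR values were low in the same region, with 20 features (30.8%) in the lowest 10% in GM12878 and 17 (26.2%) in K562 (Fisher's exact test, adjusted p = 2.14e-05 and 0.000566). G10 values were high, with 20 features (30.8%) in the highest 10% in GM12878 and 17 (26.2%) in K562. PABP passed in neither direction in either line. Of the 65 features 1 was marked present for Imp, and none for PABP or G10. Another window of high Imp values lay at 75 to 76 Mb of chromosome 7, with 9 of 16 features (Fisher's exact test, adjusted p = 0.00816).

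**Figure D4:**
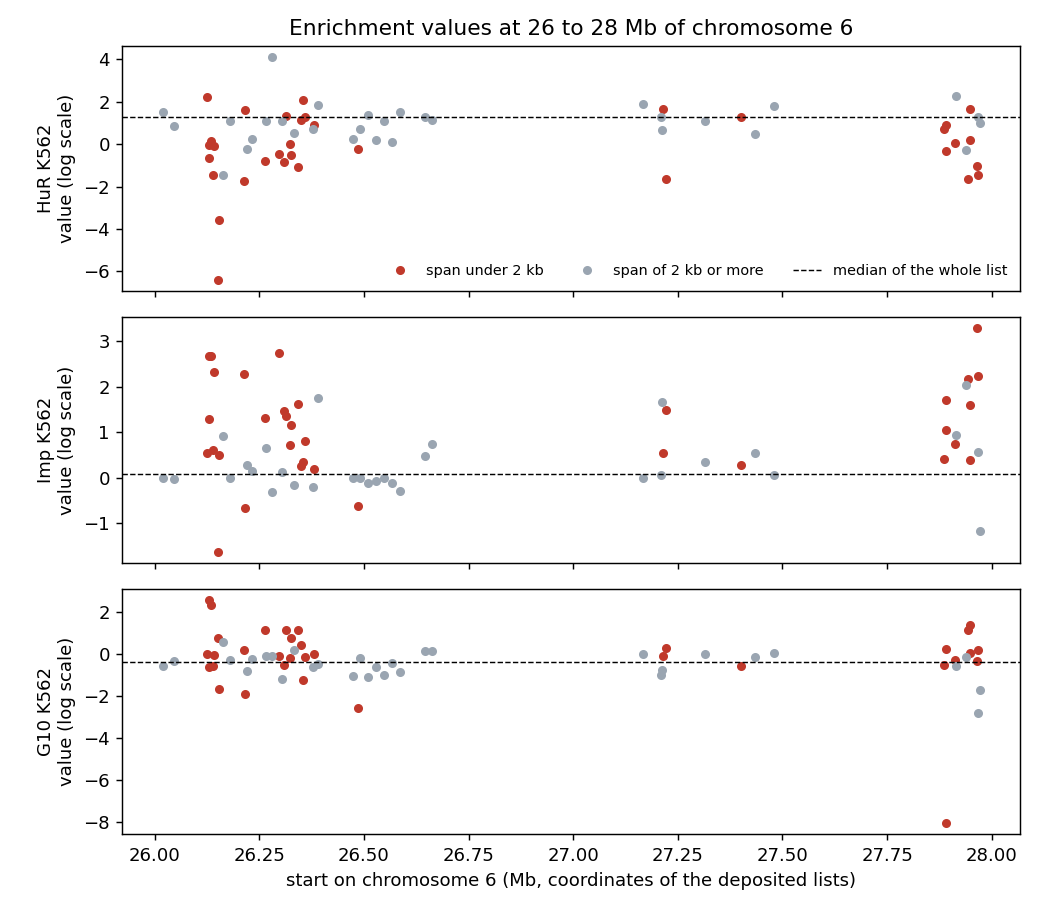
Enrichment values on a log scale for HuR (top), Imp (middle) and G10 (bottom) in K562 against the start of each of the 65 features at 26 to 28 Mb of chromosome 6, with features under 2 kb in red, longer ones in grey and the median of the whole list dashed. In Imp the features under 2 kb had a median of 1.11 and the longer ones 0.06.

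The 7 features of the mitochondrial chromosome, whose RNAs are made inside mitochondria, had low HuR and PABP values and high Imp values. Their median HuR value was 0.59 in GM12878, against 2.24 for the list, and -0.31 in K562, against 1.29 (permutation test, adjusted p = 0.00821 in each line, all 7 features below the list median). For PABP it was 0.56 against 1.09 in GM12878 (permutation test, adjusted p = 0.0466, 5 of 7 features below the list median) and -0.22 against 0.79 in K562 (adjusted p = 0.00821, 7 of 7). For Imp it was 0.71 against 0.08 (permutation test, adjusted p = 0.0163), with 6 of 7 features above the list median. G10 did not pass in either line (permutation test, adjusted p = 0.626 and 0.313). A single mitochondrial feature, 4434 to 15868 on the minus strand, was marked present, in all 7 lists, and it had the lowest Imp value of the 7, -0.65 in the authors' deposited table.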

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

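No paired analysis was possible because no values for single arrays were used here, and for the same reason no array was left out and no other split of the arrays was tried. Alternatives that need gene symbols or 3′ UTRs (1 feature per symbol, features without a symbol, all gene-list and UTR settings) were not run. For 60 alternative values the outcome was fixed beforehand and says nothing on stability: with no feature past the adjusted p, a fold of 1.5 or 4, the union of features, matching by coordinates or leaving out features enriched for G10 in K562 can only give 0, as can an overlap at a deposited p of 0.001 where either list is empty. Of the other 147, 33 kept their side of the threshold or their size, 108 moved and 6 changed sign. The 108 do not measure stability alone. Features listed counted as moved whenever they were cut to those marked present. Most overlaps, those of the 500 highest features among them, were set against a count of 0 at the adjusted p, so any shared feature counted as moved. Alternatives that use the deposited p for overlaps, the deposited p with a fold of 4, the 500 highest features for HuR, PABP or Imp with G10, an adjusted p of 0.1, the mark for presence, centring, values other than 0, spans, windows or mitochondrial features were chosen after seeing the data. The cause of a change was not tested except where stated. The low mitochondrial values of HuR and PABP and the high ones of Imp passed in the same lists without the feature marked present, while the difference for G10 in GM12878, which did not pass, changed sign from 0.14 to -0.00015. The precision of weak features is limited by signal over background, which was not given; 12216 features were marked present in no list.

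The 17880 features listed came down to those marked present: 5151 and 3808 for HuR in GM12878 and K562, 1883 and 225 for PABP, 2675 for Imp, and 2277 and 944 for G10. The count of 0 enriched features rested on the adjustment. At the deposited p of 0.05 it became 10201 and 9531 for HuR, 7282 and 2176 for PABP, 983 for Imp and 78 for G10 in K562. At the deposited p of 0.001 it was 6 and 129 for HuR, 65 for PABP in GM12878, 64 for Imp, and 0 for PABP and G10 in K562. At an adjusted p of 0.1 it was 12811 and 10277 for HuR and 0 in the other lists. At the deposited p of 0.05 with a fold of 4 it was 8921 and 2151 for HuR, 2035 and 191 for PABP, 91 for Imp and 12 for G10 in K562. With only features marked present it was 3967 and 1682 for HuR, 1087 and 0 for PABP, 308 for Imp and 9 for G10. With values centred on the list median it was 4106 and 1318 for HuR, 1775 and 279 for PABP, 832 for Imp and 144 for G10.

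The overlap of 0 between enriched lists also rested on the adjustment. For HuR between the lines it was 197 among the 500 highest features, 6654 at the deposited p and 172 in the highest 10% of features marked present in both, and for PABP 236, 1053 and 15 in the same order. The last setting compared fewer features, so its counts are smaller by design. From the 500 highest to that setting the odds ratio went from 36.6 to 16.3 for HuR and from 58.0 to 74.6 for PABP. In the same order of settings the overlap was 22, 3871 and 22 for HuR and PABP in GM12878, and 21, 1771 and 1 in K562. In K562 it was 26, 158 and 33 for HuR and Imp, and 161, 81 and 11 for PABP and Imp. With G10 in K562 it was 23, 13 and 10 for HuR, 139, 10 and 13 for PABP, and 134, 61 and 34 for Imp. The G10 list of GM12878 had no p, so its overlaps were those of the 500 highest features, and in the highest 10% of features marked present they moved from 58 to 37 with HuR, from 180 to 106 with PABP and from 146 to 32 with G10 in K562, where fewer features were compared. The odds ratio went from 5.03 to 1.92 with HuR, from 30.0 to 33.4 with PABP and from 19.8 to 8.01 with G10 in K562.

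Over features marked present in both lists the correlation moved from 0.63 to 0.81 for HuR between the lines, from 0.61 to 0.85 for PABP and from 0.29 to 0.57 for G10. It moved from 0.016 to 0.036 for HuR and PABP in GM12878, from 0.56 to 0.83 for PABP and G10 in GM12878, and from 0.55 to 0.83 in K562. In K562 it moved from 0.43 to 0.54 for PABP and Imp, from 0.34 to 0.52 for Imp and G10 and from -0.051 to -0.021 for HuR and G10, and it changed sign from -0.09 to 0.17 for HuR and Imp. Over features past the deposited p in both lists it was 0.61 for HuR and 0.79 for PABP between the lines, 0.19 for HuR and PABP in GM12878 and 0.30 in K562. In K562 it was 0.60 for PABP and Imp, 0.62 for Imp and G10 and 0.055 for PABP and G10 (15 features), and it changed sign to 0.18 for HuR and Imp and to 0.17 for HuR and G10 (32 features). Without values of exactly 0 it moved to 0.444 for PABP and Imp and to 0.356 for Imp and G10, and stayed within its interval for the other 6 of the 8 pairs tested, those of Imp or G10 within a line and of G10 between the lines.

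The rank correlation of value with span moved, among features marked present, from 0.27 to 0.014 for HuR in GM12878, from -0.14 to -0.36 and from -0.16 to -0.35 for PABP, from -0.15 to -0.24 for Imp and from -0.01 to -0.28 for G10 in K562. It changed sign from 0.08 to -0.00095 for HuR in K562, where the interval included 0, and from 0.10 to -0.18 for G10 in GM12878. With windows of 2 Mb, the windows of high values moved from 1 to 2 for HuR in GM12878, from 1 to 4 for PABP in K562, and from 1 to 2 for G10 in each line, and those of low values from 16 to 30 and from 3 to 5 for HuR, from 2 to 4 for Imp, and from 1 to 6 and from 0 to 1 for G10. With the outer 5% of features, the windows of high values moved from 1 to 0 for HuR and for PABP in each line, and those of low values from 16 to 5 and from 3 to 1 for HuR, from 2 to 0 for PABP in GM12878, from 2 to 0 for Imp, and from 1 to 3 and from 0 to 1 for G10. The 3 windows of high Imp values named above passed in both settings.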

Other observations

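The tests of the likeness of PABP and G10 were chosen after the correlations had been seen, and those of chromosome 6 and of feature density were written before their results but after the windows had been seen. The mark for presence was nested in K562: all 944 features marked for G10 and all 225 marked for PABP were also marked for Imp, while 22 of the 944 and 4 of the 225 were not marked for HuR, the longer list. In GM12878, 532 of the 2277 features marked for G10 were not marked for PABP. The Imp list held 2703 values of exactly 0, of which 127 were at features marked present, and all 2703 had a -log10 p of 0. The G10 lists held 125 in GM12878 and 224 in K562, and the HuR and PABP lists held none. Whether these zeros are placeholders is not given in the sources used here; without them the Imp median was 0.13 in place of 0.08. None of the 225 features marked for PABP in K562 had a deposited p of at most 0.05, although 22 had a value of at least 1. The window at 55 to 56 Mb of chromosome 11 held 30 features, of which 12 were in the lowest 10% for PABP in GM12878, 11 in the lowest 10% for Imp, and 12 in the highest 10% for G10 in K562 (Fisher's exact test, adjusted p = 0.0129, 0.0358 and 0.0129). With the outer 5% of features, G10 still passed (Fisher's exact test, adjusted p = 0.00208), and PABP and Imp did not (0.131 each).

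PABP values followed G10 values across features in both lines. PABP of each line also correlated with G10 of the other line, 0.23 at the lower of both values. Shared input arrays are therefore not the whole cause if each list was set against arrays of its own line, which is not given. Undetected features cannot be the whole cause, because the correlation over features marked present in both was 0.83 at the lower of both lines. The correlation of HuR with G10 was at most 0.47 times that of PABP. This cannot exclude a signal common to every immunoprecipitation, because signal of HuR's own would also lower its correlation with G10. Such a common signal, RNA abundance, array day and a background that PABP, Imp and G10 share but HuR lacks stay open. No biological explanation was tested.

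Imp values were high at 26 to 28 Mb of chromosome 6. The region's median of 0.54 lay at the percentile of 100 among 10000 random sets matched on span. Features of such spans were not high in general (matched median 0.13). The region was chosen for its high Imp values, so the percentile alone cannot set span aside. In GM12878 and K562 the percentiles were 100 and 99.67 for G10, 2.11 and 0 for HuR, and 67.2 and 8.13 for PABP. A candidate explanation of the high Imp values is short single-exon genes such as histone genes. Features under 2 kb in the region had a median 1.05 higher than longer ones (34 and 31 features, permutation p = 4.00e-05, two-sided). Features under 2 kb elsewhere had a median of 0.14. Signal also seen in G10 and signal of Imp cannot be told apart here, because 26.2% of the region was in the highest 10% for G10 in K562, between the share in Imp (36.9%) and a lack of excess. HuR was lower in these short features than in the longer ones (differences of -1.86 in GM12878 and -1.15 in K562), and the PABP medians of 1.46 in GM12878 and 0.76 in K562, against 0.88 and 0.81 for short features elsewhere, decide nothing, as no feature of the region was marked present for PABP. This remains a hypothesis, because the features are unnamed, only 1 of the 65 was marked present for Imp (2 and 1 for HuR), and cross-hybridisation between near-identical genes was not tested.

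HuR values were low in feature-dense windows, with rank correlations of value and number of features per 1 Mb of -0.31 in GM12878 and -0.16 in K562. Span did not account for all of it, as the partial correlation given span was weaker but remained, at -0.21 in GM12878 and -0.14 in K562. Undetected features did not account for all of it either: over features marked present it was -0.25 in GM12878 (95% interval -0.282 to -0.216, resampling windows) and -0.11 in K562 (-0.143 to -0.0753), though the K562 interval reaches past the -0.10 set beforehand. It was not particular to HuR: G10 had -0.15 and -0.08 over all features, and over marked features given span the values were -0.27 and -0.12 for HuR, -0.12 and -0.17 for PABP, -0.06 for Imp, and -0.25 and -0.16 for G10, although PABP (0.11 and 0.06) and Imp (0.08) had positive values over all features. GC content, which rises with gene density, and U content of the transcripts stay open, as no sequence was used here.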
